A study of Mus musculus with 8 samples.

How the data were processed

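Total RNA from mouse liver was measured on 8 Agilent 1-colour (Cy3) whole-genome arrays, 1 array for each of 2 genotypes at each of 4 times (0, 24, 36 and 48 h after partial hepatectomy). Mxcre-positive livers were taken as Survivin-deleted and Mxcre-negative livers as wild type, from the genotype labels and the series design, and the level of Birc5 was used to check this. Times are those of the sample titles; a protocol note in the labels names a later time of analysis, which was not used. Each genotype and time had 1 array, so no spread between replicate livers can be given. The labels do not say whether an array held RNA of 1 animal or of a pool, and they give the sex as male or female without saying which for which sample.

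The scanner files hold fluorescence intensity per spot. Per the file headers, the processed signal is an intensity that Feature Extraction 10.7.3.1 (10.7 in the authors' notes) had background-subtracted and spatially detrended, without normalisation between arrays. The deposited matrix of values holds log2 values; their scale is not stated there and was found from the values. All 8 columns had the same median (5.51) and nearly the same sorted values, and each correlated with log2 of the processed signal of its own array at r of at least 0.999 (at most 0.984 with any other array), across spots, which are not independent replicates. It was therefore read as quantile-normalised log2 signal and used only as an alternative source. No matching of columns to arrays was left open (0 unmatched).

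Main values were log2 of the processed signal minus the 75th percentile of the array. Control spots were removed. Spots marked as outliers were left out of a probe's mean. Of 41174 probes, 118 with no unmarked spot on at least 1 array were left out and 41056 kept. Of these, 26839 carried an accession found in the RefSeq table, which gave 18316 genes, 6502 of them with more than 1 probe; the probe with the highest mean signal stood for the gene. Unnamed probes were left out. Genes well above background on at least 2 of the 8 arrays entered the tests (14142 genes). Each array had 43379 spots, of which 60.2% to 66.0% were well above background. The median coefficient of variation of replicate spots was 4.45% to 6.51%. The number of arrays limits the precision. Signal near background limits the folds of dim genes: where a gene was not above background on any array of the dimmer side, the fold is given as a lower bound against the background level. Where only some arrays of the dimmer side were not above background, those arrays were set at that level for a bound, which took no account of dim arrays on the other side.

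Tests used limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table. An additive model with time as a factor and genotype (3 residual degrees of freedom) gave the genotype difference, averaged over the 4 times, and each time against 0 h. A model with genotype by after-hepatectomy as a further term (2 residual degrees of freedom) tested whether the difference after surgery was other than at 0 h. There 0 h had 1 pair of arrays, so its spread was not measured and was taken to be that of the later pairs. In these fits p measures how steady a difference was over the times or between the genotypes, since no group had replicates. Genes were called at a Benjamini-Hochberg adjusted p of 0.05. The differences within each time had no test and are given by size, with a list's median placed among 10000 random lists of like expression.

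Before the data were examined, 35 gene lists (676 genes, 616 measured) were fixed from general knowledge; 34 had at least 3 measured genes and were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry. Fry's directional p asks whether a list's genes move, on balance, to 1 side, and its mixed p whether they change in either direction; neither compares a list with other genes. No camera call in any comparison held with an estimated correlation (0 lists). On simulated changes the genotype test recovered 51.5% of 2-fold and 85.5% of 4-fold changes. The time tests recovered 0% of 2-fold and 70.5% to 73% of 4-fold changes. The test of a changed difference recovered 0% of 4-fold and 45% of 8-fold changes. Each simulation held 200 equal, steady changes in genes that varied independently, with spreads estimated from these arrays and no other effects. The real tests differ in all of these, so the rates do not give their power.

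The named genes followed a rule set before the data were examined. For genotype these were the 10 genes in each direction with the largest mean change past the threshold and 1 sign at all 4 times, filled up by the smallest unadjusted p where fewer passed. For each time they were the 5 largest changes in each direction past the threshold with 1 sign in both genotypes. For the changed difference they were the 5 smallest p in each direction, and for each single time the 5 largest differences in each direction. Of each described list up to 4 members with the largest change were named. Clone names were passed over.

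The alternatives tried were quantile and median scaling, normexp background correction (offset 50) with quantile normalisation, the deposited matrix of values, the mean of all probes, trended and robust variances, no filter or a stricter filter on dim genes, other blocks (slide, no time, no genotype), leaving out arrays or pairs in turn, other thresholds and groupings of times, other set tests, and the Y-linked transcripts as a covariate. Normexp used the median spot signal, since the files hold no mean signal. Scaling by the array median moved the median change of all genes from -0.05 to 0.12 (log2) for 36 h and from -0.07 to 0.07 for 48 h, and the median genotype difference at 0 h from -0.02 to 0.09. The arrays of 0 and 24 h were on 1 slide and those of 36 and 48 h on the other, with both genotypes on each, and each slide had its own scan.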

Results

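Liver gene expression was measured in mice in which Survivin (Birc5) could be deleted by Mxcre, a Cre recombinase switched on by poly(IC) through an interferon response. The animals had also been irradiated and given a bone marrow transplant, per the labels. Partial hepatectomy removes part of the liver and makes the remaining hepatocytes divide. Livers were compared at 0, 24, 36 and 48 h after it, with 4 Mxcre-positive and 4 Mxcre-negative arrays. Levels below are log2 intensities relative to the 75th percentile of the array, errors are standard errors (SE) of the limma fit, and adjusted p values are limma's.

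Birc5, which encodes an inhibitor of apoptosis protein needed for chromosome segregation and cytokinesis, was lower in the Mxcre-positive liver at each of the 4 times. The gene lies on chromosome 11 and was read by 1 probe that was above background on all 8 arrays. In Mxcre-negative liver its level was -0.20 at 0 h, -0.48 at 24 h, 1.61 at 36 h and 5.10 at 48 h. In Mxcre-positive liver it was -2.75, -3.42, -1.51 and -1.14 at the same times. Birc5 was thus 5.85-fold lower at 0 h, 7.71-fold lower at 24 h, 8.68-fold lower at 36 h and 75.4-fold lower at 48 h. The fitted difference over the 4 times was -3.71 ± 0.67 (log2, SE), which did not pass over all genes (limma adjusted p = 0.751). Which part of the transcript the probe reads relative to the deleted part was not examined.

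**Figure D1:**
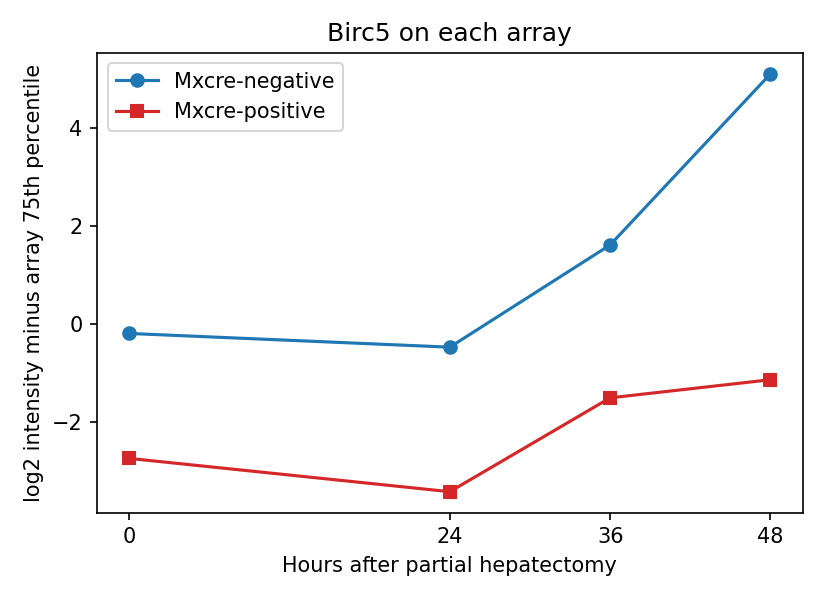
Level of Birc5 on each of the 8 arrays (log2 intensity minus the array's 75th percentile) against hours after partial hepatectomy, with circles for Mxcre-negative and squares for Mxcre-positive liver. The level reached 5.10 in Mxcre-negative and -1.14 in Mxcre-positive liver at 48 h.

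Transcripts of the sex chromosomes differed between arrays, and this ran along with time and genotype. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were not above background on either 0 h array or on the Mxcre-positive arrays of 36 and 48 h. Their mean level was -0.79 and -1.30 on the Mxcre-negative and Mxcre-positive 24 h arrays, -1.49 on the Mxcre-negative 36 h array and -0.69 on the Mxcre-negative 48 h array, against -6.04 to -6.57 on the other 4. Xist, the transcript of the inactive X chromosome, was 5.16 to 5.55 on the arrays without Y-linked signal. On the arrays with it, Xist was 3.55 (Mxcre-negative, 24 h), 4.27 (Mxcre-positive, 24 h), 4.44 (36 h) and 2.38 (48 h). The genotype pairs of 36 and 48 h and the comparison of 24 h with 0 h therefore also differed in Y-linked signal. So did the comparisons of 36 and 48 h with 0 h, through their Mxcre-negative arrays.

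**Figure D2:**
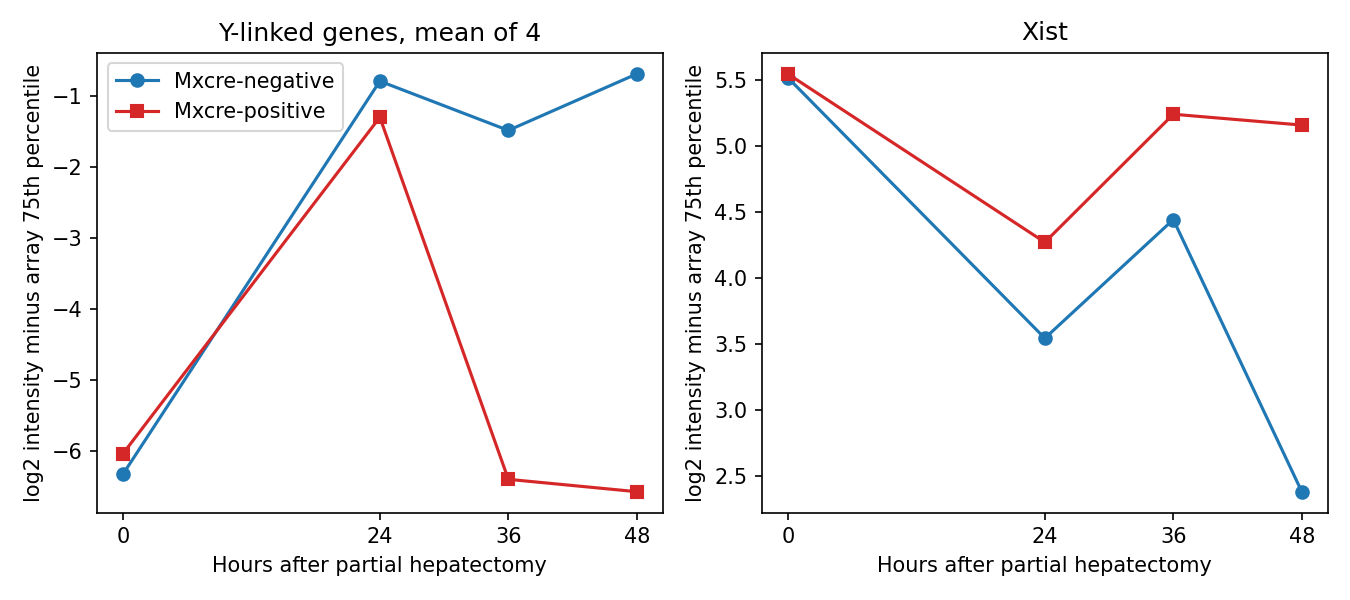
Mean level of 4 Y-linked genes (left) and level of Xist (right) on each array, in log2 intensity minus the array's 75th percentile, against hours after partial hepatectomy. Circles are Mxcre-negative and squares Mxcre-positive livers, and the y axes of the panels differ.

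The comparison of Mxcre-positive with Mxcre-negative liver over the 4 times asks which genes differed on average over the times. Transcripts of fatty acid oxidation were higher and those of mitosis lower in Mxcre-positive liver as groups, and those of DNA replication lower at 36 and 48 h alone, while no single gene passed. Of 27 genes of fatty acid oxidation and PPAR alpha targets, 26 had a positive difference (median 0.35), with Fgf21, a fasting hormone, at 1.28 ± 0.75, Vnn1 at 1.00 ± 0.16, Ehhadh at 0.92 ± 0.26 and Cyp4a10 at 0.87 ± 0.26. None of the list's genes passed over all genes and 3 were higher adjusted over the list alone (camera adjusted p = 6.52e-11, and adjusted p = 0.495 with an estimated correlation). Genes of the unfolded protein and heat shock response (below, the unfolded protein list) were positive in 18 of 20 members (median 0.29), with the chaperone Hspa5 at 0.74 ± 0.21 and Ddit3 at 0.73 ± 0.23, but Asns, an amino acid response gene, at -0.95 ± 0.25. Its medians were 0.70, 0.33 and 0.20 at 0, 24 and 36 h and then -0.26 at 48 h, with 16 of 20 lower there. That list had a camera adjusted p of 0.000248 (adjusted p = 0.789 with an estimated correlation), with 0 genes adjusted over the list alone.

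Mitosis and cytokinesis genes were negative in 36 of 38 members (median -0.40, or -0.24 with 20 members at a bound on some arrays). Among them were Racgap1 at -1.60 ± 0.70, the proliferation marker Mki67 at -1.13 ± 0.42, the motor Kif11 at -0.84 ± 0.24 and the checkpoint kinase Bub1b at -0.81 ± 0.28. With the arrays not above background at their bound, Racgap1, Kif11 and Bub1b were at least 0.63, 0.33 and 0.25 lower (log2), and Mki67 was above background on all arrays. The camera adjusted p was 7.38e-09 (adjusted p = 0.495 with an estimated correlation), with 0 genes lower over all genes and 1 adjusted over the list alone. All 35 measured genes of DNA replication and S phase were negative (median -0.52), with Mcm10 at -1.13 ± 0.19 and Cdc6 at -1.02 ± 0.44 (at least 0.26 lower at its bound), both of which act in starting replication. Camera gave that list an adjusted p of 9.5e-09 (adjusted p = 0.797 with an estimated correlation), and 0 genes passed adjusted over the list alone. The call rested on the pairs of 36 and 48 h, which differed in Y-linked signal, and with the Y-linked covariate it ended (median 0.01, camera adjusted p = 0.386). That loss does not point to sex, since the covariate takes up any difference confined to these 2 pairs. The 3 partners of Survivin in the chromosomal passenger complex were also negative, Aurkb at -0.61 ± 0.27, Incenp at -0.59 ± 0.16 and Cdca8 at -0.51 ± 0.20 (camera adjusted p = 0.0092, and adjusted p = 0.682 with an estimated correlation), with 1 lower adjusted over the list alone. At its bound Aurkb kept no difference (0.00).

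Urea cycle and amino acid catabolism genes were negative in 22 of 23 members (median -0.22), with the methyltransferase Bhmt at -0.54 ± 0.10 (camera adjusted p = 3.09e-06, and adjusted p = 0.495 with an estimated correlation). T and NK cell markers had a median of -0.51 (-0.17 with 10 members at a bound on some arrays), with 14 of 18 negative, Klrd1 at -1.05 ± 0.36, but the cytotoxic effector Prf1 at 1.00 ± 0.37 (camera adjusted p = 0.00126, and adjusted p = 0.495 with an estimated correlation). At their bounds Klrd1 was at least 0.12 lower and Prf1 at least 0.78 higher. Cholesterol synthesis genes had a median of 0.40 (camera adjusted p = 0.000899), carried by the pair of 48 h (-0.09, 0.11, -0.26 and 1.60 at the 4 times), and fatty acid and triglyceride synthesis genes 0.15 (camera adjusted p = 0.00126; 0.08, -0.08, 0.31 and 0.60 at the 4 times). With an estimated correlation these were adjusted p = 0.979 and adjusted p = 0.789. In each of these 4 lists 0 genes passed over all genes and 0 adjusted over the list alone.

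Lists tied to sex moved as well. The 14 male-biased liver genes had a median of -0.55, with Elovl3 at -2.42 ± 0.85 and Hsd3b5 at -2.37 ± 0.91 (camera adjusted p = 0.000899, and adjusted p = 0.864 with an estimated correlation). The 16 female-biased genes had a median of 0.21, from -0.08 at 0 h to 0.84 at 48 h (camera adjusted p = 0.0147, and adjusted p = 0.789 with an estimated correlation). The 4 Y-linked genes had one of -2.66, or -1.69 with all 4 at a bound on some arrays (camera adjusted p = 0.0092, and adjusted p = 0.789 with an estimated correlation). With the Y-linked transcripts as a covariate, the fatty acid oxidation, unfolded protein, mitosis, urea cycle and T and NK cell lists kept their calls and directions (5 of 12). The S phase, cholesterol, fatty acid synthesis and male-biased lists were not called there (camera adjusted p = 0.386 to 0.938). Their medians had the opposite sign but were small (0.01, -0.07, -0.05 and 0.06). The Y-linked list was tested with its own mean as the covariate, so the loss of its call (median -0.01) was fixed beforehand. The passenger partners (median -0.27) and female-biased genes (0.02) kept their direction without a call (camera adjusted p = 0.144 and 0.938). Lists called only with the covariate were the neutrophil markers (median -2.08, camera adjusted p = 1.32e-14), macrophage markers (-0.52, 6.39e-06), interferon-stimulated genes (-0.25, 0.00124) and progenitor markers (-0.09, 0.0168), all lower, and stellate cell markers (0.12, 0.0168), which were higher. With an estimated correlation none of the 5 was called (adjusted p = 0.643 to 0.785). In the pairs of 0 and 24 h, which were alike in Y-linked signal, the same 5 of 12 lists kept their calls, 7 did not, and the camera adjusted p of the S phase list was 0.479. This is no separate check, since Y-linked signal differed clearly within pairs only at 36 and 48 h. The covariate fit thus took its genotype difference mainly from the pairs of 0 and 24 h. Any difference confined to the late pairs was lost in it, whatever its cause. The cholesterol list was not called without the pair of 48 h (camera adjusted p = 0.550). The p53 targets, among them the cell cycle inhibitor Cdkn1a at 0.31 ± 0.27, had a median of -0.01 (camera adjusted p = 0.999), and the apoptosis regulators -0.07 (camera adjusted p = 0.645). The interferon-stimulated genes had a median of -0.03 in the main fit (camera adjusted p = 0.953), which averaged -0.45 at 0 h (24 of 27 lower), -0.14 at 24 h, 0.44 at 36 h (24 of 27 higher) and -0.08 at 48 h.

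Over all genes limma called 0 of 14142 for genotype, with the smallest adjusted p at 0.418, and 932 genes had an unadjusted p under 0.05 (313 higher, 619 lower, against 707 expected by chance). With the genotypes swapped within 1 or more times, 328 to 895 genes had such a p. The real grouping gave the most, but with 8 groupings in all this cannot tell whether the excess is a genotype effect. The same sign at all 4 times was seen in 2272 genes, or 16.1%, where chance gives 12.5% if the times are independent. The steadiest higher genes, none of which passed, were Kdelr3, a receptor that returns proteins to the endoplasmic reticulum, at 1.61 ± 0.12, Mc5r at 1.40 ± 0.12, Raet1e at 1.12 ± 0.12, Hhipl2, Ccn1, Vnn1, Net1, Hsdl2, Lrfn3 and Fkbp11 (limma adjusted p = 0.418 to 0.751). Mc5r was above background on 3 of the 8 arrays, and Kdelr3, Mc5r and Raet1e were at least 1.09, 0.33 and 0.99 higher at their bounds. The steadiest lower genes, which did not pass either, were Cenps, a kinetochore protein, at -0.92 ± 0.10, Slc4a1, the red cell anion exchanger, at -0.65 ± 0.09, the mitotic motor Kif4 at -0.78 ± 0.10, Pi16, Apol10b and Tmem221. At their bounds Cenps was at least 0.29 and Kif4 at least 0.67 lower. With them stood Il1f10, Tulp2, Ccdc173 and Hpcal4, which were not above background on any Mxcre-positive array and were at least 1.36-fold, 1.05-fold, 1.24-fold and 1.08-fold lower.

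At the single times, each a pair of arrays without a test, the S phase genes differed late and neutrophil and macrophage markers changed side. The median difference of the S phase list was 0.15 at 0 h (0.05 with dim members left out or at their bound), 0.01 at 24 h, -0.87 at 36 h and -1.12 at 48 h. All 35 genes were lower at both late times (percentile 0 among random lists). Mitosis genes had medians of -0.17, -0.66, -0.52 and -0.24, with 19 and 13 of the 38 not above background on either array at 0 and 24 h. With these left out and other dim members at their bound the medians were -0.05, -0.65, -0.50 and -0.24. Neutrophil markers were lower in Mxcre-positive liver at 0 h (median -2.99, or -2.61 with 2 dim members at their bound) and 24 h (-0.91) and higher at 36 h (1.31) and 48 h (1.77). Macrophage markers had medians of -0.79, -0.33, 0.78 and 0.04, and hepatocyte markers stayed between -0.11 and 0.01 at all 4 times. T and NK cell markers (-0.76, -0.15, -0.25 and -0.43) and erythroid markers (-0.19, -0.40, -0.36 and -0.26) had negative medians at each time. The T and NK cell medians at 24 and 36 h lay at percentiles 17 and 33 among random lists. With dim members left out or at their bound the T and NK cell medians were -0.78, -0.08, -0.09 and -0.31, and the erythroid median at 36 h was -0.12. B cell markers had medians of -0.62, 0.26, 0.00 and -0.32. All 22 cholesterol synthesis genes were higher at 48 h (median 1.60).

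**Figure D3:**
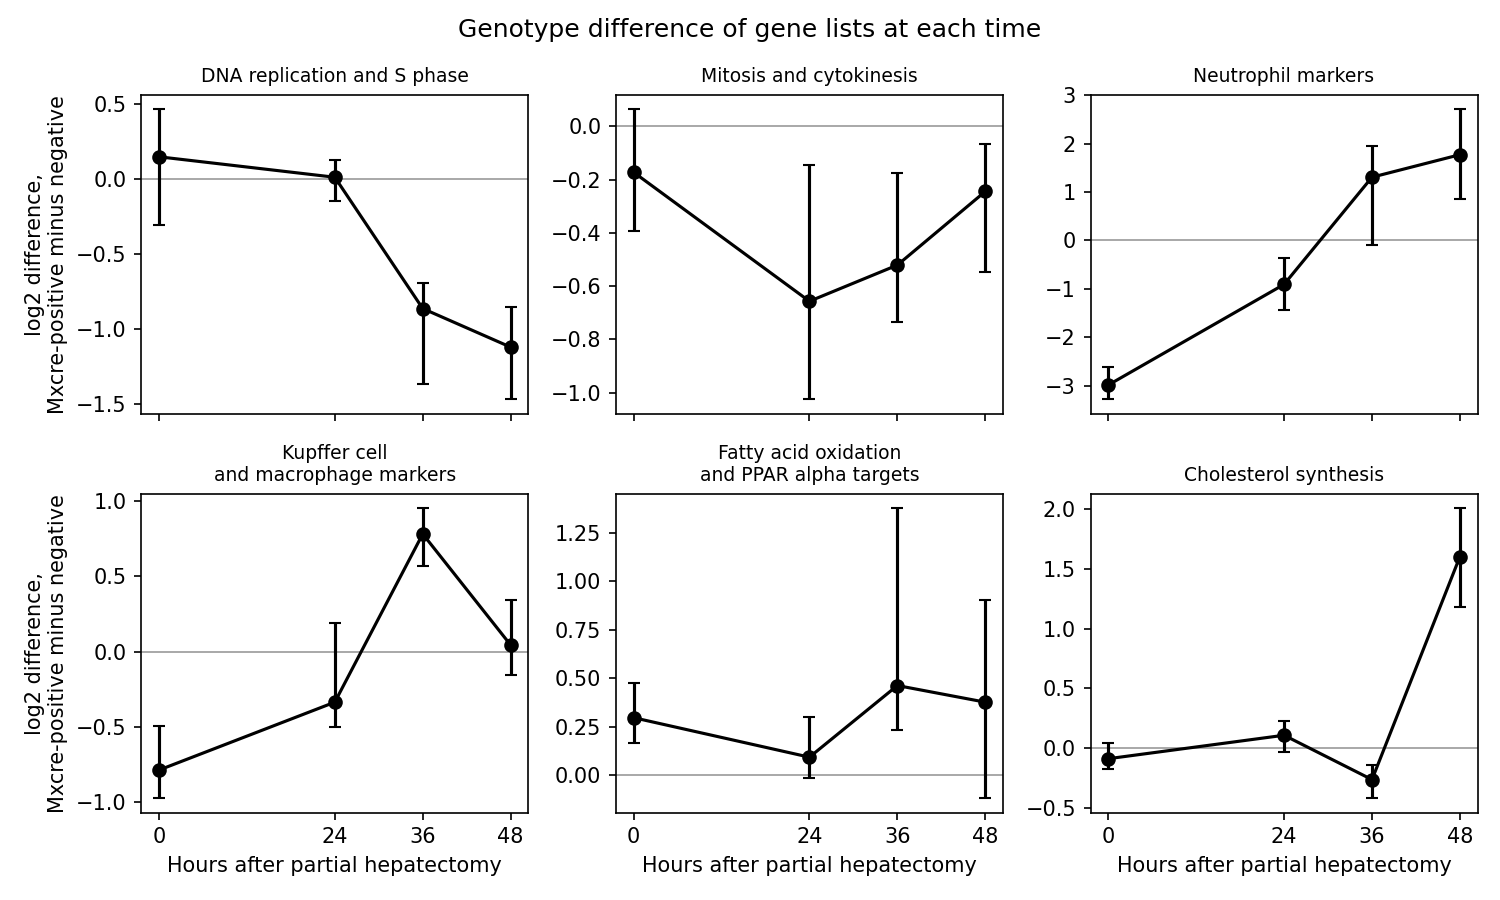
Median log2 difference, Mxcre-positive minus Mxcre-negative, of 6 gene lists at each time, with bars from the lower to the upper quartile over the list's genes; y axes differ between panels. S phase genes reached -1.12 and neutrophil markers 1.77 at 48 h.

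Among single genes, 339 were lower and 153 higher by 2-fold or more at 0 h, 152 and 102 at 24 h, 301 and 282 at 36 h, and 413 and 319 at 48 h (genes above background on both arrays). At 0 h Ppp2r5a, Dct, Tuba3a, Pde6h and Angel2 were furthest down and Jph3, the heat shock gene Hspa1a, Tex43, Hoxa4 and Nat8f5 furthest up. The spots of Ppp2r5a, Tuba3a and Angel2 departed on the Mxcre-positive 0 h array alone, as given below for the changed differences. At 24 h the interleukin-1 antagonist Il1rn (2.73), Hao2, Cbln1, Olfr391 and Prom2 were higher, and Hsd3b5 (-4.72), Larp6, Elovl3, Reg3b and Birc5 lower. At 36 h Cyp8b1, the sterol 12-alpha-hydroxylase (4.43), Xxylt1, Adh6-ps1, Asic5 and Epgn were higher, and Cyp4a12a (-4.86), Nat8f5, Cfd, Grip2 and Myom2 lower. At 48 h Rgs16 (4.94) and the sulfotransferases Sult2a4, Sult3a2, Sult2a3 and Sult2a6 were higher, and Cyp4a12a (-6.30), Birc5, Elovl3, Kcnn4 and Nat8 lower. Cyp4a12a, Elovl3 and Hsd3b5 are male-biased and the Sult2a genes female-biased in mouse liver, and the pairs of 36 and 48 h differed in Y-linked signal. Male-biased genes had medians of 0.30, -0.30, -0.80 and -1.40 over the 4 times.

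At 24 h against 0 h the growth gene and p53 target lists were called up and the urea cycle, fatty acid synthesis and bile acid lists down. Of the 38 mitosis genes 3 rose, and of the 35 S phase genes 2 fell (camera adjusted p = 0.104 and 0.620). Cidec, a lipid droplet protein, rose 69.3-fold (log2 6.11 ± 0.74, limma adjusted p = 0.0242), the chemokine Cxcl14 53.2-fold, and Itgb6, an integrin, Capn8 and Retnla rose at least 23.3-fold, at least 18.0-fold and at least 22.0-fold. Inmt fell 131-fold (log2 -7.04 ± 0.47, limma adjusted p = 0.0173), Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 131-fold, the hepcidin gene Hamp2 110.0-fold, Upp2 84.3-fold and Slc22a26 54.4-fold. Of 19 G1 cyclin and growth genes 7 rose, and 13 rose adjusted over the list alone, among them Egr1 (3.47 ± 0.31) and Fos (2.23 ± 0.30), both immediate early transcription factors (camera adjusted p = 2.51e-05, and adjusted p = 0.414 with an estimated correlation). Of 23 p53 targets 5 rose (9 up and 2 down adjusted over the list alone), with Cdkn1a at 3.71 ± 0.37 and the stress cytokine Gdf15 at 2.22 ± 0.36 (camera adjusted p = 0.00453, and adjusted p = 0.414 with an estimated correlation). Acute phase proteins had a median of 0.95, with Lcn2 (4.01 ± 0.80) and Saa3 (3.92 ± 0.73) up, 2 up and 1 down over all genes, and 12 up and 2 down adjusted over the list alone (camera adjusted p = 0.000353, and adjusted p = 0.697 with an estimated correlation).

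Of the 23 urea cycle and amino acid genes 11 fell by 24 h, and 15 adjusted over the list alone (1 rose there), with Prodh at -1.97 ± 0.25 and Otc, a urea cycle enzyme, at -1.57 ± 0.15 (camera adjusted p = 1.45e-05, and adjusted p = 0.414 with an estimated correlation). Of 21 fatty acid synthesis genes 8 fell, and 12 adjusted over the list alone, with Thrsp at -5.27 ± 0.45 and the lipogenic regulator Srebf1 at -2.26 ± 0.24 (camera adjusted p = 2.98e-05, and adjusted p = 0.568 with an estimated correlation). All 22 cholesterol synthesis genes were negative (median -0.90), though 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.00171, and adjusted p = 0.705 with an estimated correlation). Bile acid genes fell in 4 of 19, cytochrome P450 genes in 6 of 30 and female-biased genes in 7 of 16 (8, 13 and 8 adjusted over the list alone; camera adjusted p = 0.0126, 0.0189 and 0.000666, and adjusted p = 0.414, 0.705 and 0.568 with an estimated correlation). T and NK cell markers fell in 5 of 18, with the granzyme Gzmb at -1.94 ± 0.34 and Gzma at least 2.70-fold lower, and B cell markers in 1 of 9 (camera adjusted p = 0.00453 and 0.00865, and adjusted p = 0.414 and 0.660 with an estimated correlation). Ductular markers rose in 3 of 12, Sox9 at 2.84 ± 0.36 and Spp1 at 2.84 ± 0.45, stellate cell and fibroblast markers in 3 of 22, Acta2 at 1.40 ± 0.13, and Nrf2 targets in 2 of 12, Srxn1 at 2.25 ± 0.29. Their camera adjusted p was 0.0279, 0.00248 and 0.00171 (adjusted p = 0.568, 0.697 and 0.568 with an estimated correlation). The Y-linked genes, with a median of 5.15 (4.04 with all 4 at their bound), were called as well (camera adjusted p = 0.035, and adjusted p = 0.697 with an estimated correlation). So were the plasma proteins, with a median of -0.22 and F7 at -1.52 ± 0.21 (camera adjusted p = 0.0355, and adjusted p = 0.778 with an estimated correlation).

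Over all genes 1369 of 14142 changed at 24 h (649 up, 720 down). Both 0 h arrays lacked and both 24 h arrays had Y-linked signal, and with that signal as a covariate 1 gene was called. The growth gene, p53, acute phase, urea cycle, plasma protein, Nrf2 and ductular lists kept their calls there (7 of 16). The bile acid, cytochrome P450, cholesterol, fatty acid synthesis, female-biased, Y-linked, stellate cell, T and NK cell and B cell lists did not (camera adjusted p = 0.0657 to 0.918). The Y-linked list was adjusted for its own mean there. For the others a lost call does not show that the change itself was lost or that it came from sex. Called only with the covariate were the S phase list, down (median -1.01), and the neutrophil and macrophage markers, up (4.04 and 0.73). Their camera adjusted p was 2.29e-06, 8.69e-07 and 0.0226 (adjusted p = 0.628, 0.628 and 0.772 with an estimated correlation). The arrays showed no changes of that size. The mean S phase level went from -1.14 to -0.99 in Mxcre-negative and from -0.96 to -1.03 in Mxcre-positive liver. The neutrophil level went from 0.81 to 0.18 and from -1.86 to -0.68. The slope of the covariate came from the contrast of late with early genotype pairs, and it carried their differences into the 24 h values. Leaving out 1 array gave 141 genes without the Mxcre-negative 0 h array, 514 without either 48 h array and 0 without any of the other 5. The count was 573 with no filter on dim genes, 2191 with normexp correction and 2152 with trended and robust variances. Scaling by the median of the array moved the split to 888 up and 622 down.

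At 36 h against 0 h the replication and mitosis lists were called up together, and the urea cycle, bile acid and lymphocyte lists down. Cidec rose 90.1-fold (log2 6.49 ± 0.74, limma adjusted p = 0.0189) and Aunip at least 24.4-fold, while the mitotic kinases Pbk and Cdk1 rose at least 16.7-fold and at least 11.8-fold and Fignl1 at least 18.0-fold. Hamp2 fell 49.5-fold (log2 -5.63 ± 0.17, limma adjusted p = 0.00545), Slc22a26 30.1-fold and Inmt 27.4-fold, and Ranbp3l and Raet1e fell at least 10.1-fold and at least 17.6-fold. Of 35 S phase genes 24 rose and 1 fell (32 and 1 adjusted over the list alone), with the helicase genes Mcm6 (4.82 ± 0.62) and Mcm5 (4.42 ± 0.68), the methylation factor Uhrf1 (4.99 ± 0.73) and Cdc6 (at least 11.2-fold higher) among them. Camera gave an adjusted p of 3.01e-12 (adjusted p = 0.620 with an estimated correlation). Of 38 mitosis genes 29 rose, and 32 rose and 1 fell adjusted over the list alone (camera adjusted p = 2.98e-17, and adjusted p = 0.298 with an estimated correlation), with Mki67 at 3.74 ± 0.59 and Nek2 at least 10.9-fold higher. The median of the mitosis list was 2.39, or 2.16 with 15 members at their bound and 2 left out as not above background. All 3 chromosomal passenger partners rose, Aurkb at least 5.52-fold and Cdca8 by 2.35 ± 0.28 (camera adjusted p = 0.00247, and adjusted p = 0.465 with an estimated correlation).

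**Figure D4:**
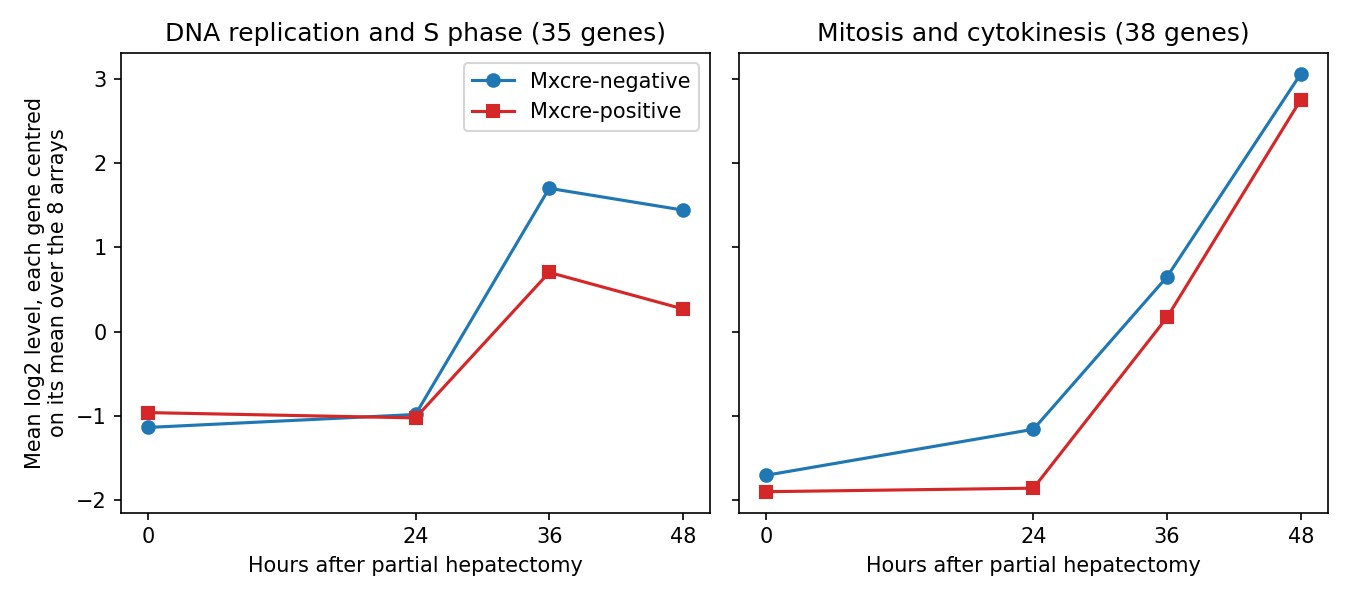
Mean level of 35 S phase genes (left) and 38 mitosis genes (right) on each array, each gene centred on its mean over the 8 arrays (log2), against hours after partial hepatectomy. Circles are Mxcre-negative and squares Mxcre-positive livers; mitosis genes were higher at 48 h than at 36 h in both.

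The p53 targets rose in 8 of 23 and fell in 2 at 36 h (15 and 3 adjusted over the list alone), with Cdkn1a at 3.05 ± 0.37 (camera adjusted p = 0.000344, and adjusted p = 0.298 with an estimated correlation). Growth genes rose in 8 of 19, with Egr1 at 3.44 ± 0.31 and Atf3 at 2.99 ± 0.51 (camera adjusted p = 3.47e-05, and adjusted p = 0.298 with an estimated correlation). Fatty acid oxidation genes rose in 9 of 27 (12 up and 2 down adjusted over the list alone; camera adjusted p = 0.000344, and adjusted p = 0.592 with an estimated correlation). Urea cycle genes fell in 9 of 23 and rose in 1, bile acid genes fell in 6 of 19 and rose in 1, and fatty acid synthesis genes fell in 4 of 21 (13, 6 and 4 fell adjusted over the list alone). Their camera adjusted p was 0.000344, 0.026 and 0.00677 (adjusted p = 0.465, 0.465 and 0.657 with an estimated correlation). T and NK cell markers fell in 8 of 18, with Cd3d at -1.63 ± 0.24 (at least 1.61 lower at its bound), and B cell markers in 4 of 9, with Cd79b at -1.76 ± 0.39 (camera adjusted p = 0.00103 and 0.00247, and adjusted p = 0.298 and 0.620 with an estimated correlation). Stellate cell markers rose in 7 of 22, with the collagen gene Col1a1 at 1.96 ± 0.40 (camera adjusted p = 0.00247, and adjusted p = 0.657 with an estimated correlation). The acute phase, Nrf2, plasma protein and female-biased lists were called in the directions seen at 24 h (camera adjusted p = 0.00421, 0.00376, 0.0252 and 0.0253, and adjusted p = 0.667, 0.620, 0.747 and 0.657 with an estimated correlation).

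Over all genes 2298 changed at 36 h (1145 up, 1153 down), 984 with the Y-linked transcripts as a covariate and 938 with no filter on dim genes. With the covariate 13 of the 16 lists kept their calls, and the bile acid, fatty acid synthesis and female-biased lists did not (camera adjusted p = 0.0785, 0.0669 and 0.119). The neutrophil markers (median 2.46) and interferon-stimulated genes (0.50) were called up only there (camera adjusted p = 9.93e-05 and 0.0152, and adjusted p = 0.654 and 0.692 with an estimated correlation). As at 24 h, these values rest on the slope that the covariate took from the genotype pairs. Without 1 array the count was 300 (Mxcre-negative 0 h), 52 (Mxcre-positive 0 h), 131 (either 24 h array), 0 (either 36 h array) and 903 (either 48 h array). The 36 and 48 h arrays were on the other slide than the 0 h arrays, so slide and time cannot be told apart in these comparisons. The Mxcre-negative arrays of 36 and 48 h also had Y-linked signal, which both 0 h arrays lacked. Scaling by the median of the array moved the split to 1875 up and 704 down.

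At 48 h mitotic transcripts were among the largest rises, and the urea cycle, bile acid and cytochrome P450 lists were called down. Pbk rose at least 67.9-fold, Cenpf, a kinetochore protein, at least 64.6-fold (limma adjusted p = 0.000718), Cdk1 at least 50.9-fold, the cyclin Ccnb1 at least 45.0-fold and the anaphase activator Cdc20 95.3-fold. Hao2, a member of the female-biased list, fell at least 97.3-fold. Hamp2 fell 106-fold (log2 -6.73 ± 0.17, limma adjusted p = 0.00127), Inmt 67.7-fold, Slc22a26 66.5-fold and Cyp7a1 63.7-fold. Of 38 mitosis genes 36 rose (36 adjusted over the list alone), with a median of 5.01, or 4.54 with 17 members at their bound (camera adjusted p = 2.17e-30, and adjusted p = 0.217 with an estimated correlation). Compared with 36 h, on the same slide, 14 genes had risen and 1 fallen, 10 of the risen ones in the mitosis list, whose median was 2.44 higher (camera adjusted p = 1.90e-53, and adjusted p = 0.157 with an estimated correlation). S phase genes rose in 23 of 35 and fell in 1 against 0 h (29 and 2 adjusted over the list alone; camera adjusted p = 5.03e-11, and adjusted p = 0.493 with an estimated correlation). Against 36 h their median was -0.21 (camera adjusted p = 0.0647, and adjusted p = 0.929 with an estimated correlation). Cdca8 (4.27 ± 0.28), Incenp (3.69 ± 0.23) and Aurkb (at least 26.3-fold) all rose (camera adjusted p = 0.000344, and adjusted p = 0.283 with an estimated correlation).

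The p53 targets rose in 15 of 23 at 48 h (16 up and 1 down adjusted over the list alone; camera adjusted p = 2.74e-07, and adjusted p = 0.217 with an estimated correlation). Among them were Ckap2 (at least 38.0-fold) and Gtse1 (at least 12.1-fold), which also act in mitosis, beside Cdkn1a (3.45 ± 0.37). Urea cycle genes fell in 14 of 23 (19 down and 1 up adjusted over the list alone), Otc at -1.93 ± 0.15, and cytochrome P450 genes fell in 14 of 30 and rose in 1, Cyp2c37 at -4.35 ± 0.47 and Cyp1a2 at -2.52 ± 0.35. Bile acid genes fell in 8 of 19 and rose in 2, among them Cyp27a1 at -2.01 ± 0.28. The camera adjusted p of these lists was 6.51e-07, 0.00307 and 0.0122 (adjusted p = 0.283, 0.541 and 0.283 with an estimated correlation). Hepatocyte markers fell in 2 of 8, Cyp2e1 at -1.62 ± 0.28, and plasma proteins in 6 of 25 (camera adjusted p = 0.0342 and 0.0122, and adjusted p = 0.361 and 0.715 with an estimated correlation). Clock genes fell in 9 of 18 and rose in 2, with Ciart at -3.39 ± 0.52 (at least 3.23 lower at its bound) and Dbp at -2.86 ± 0.33 (camera adjusted p = 0.0122, and adjusted p = 0.493 with an estimated correlation). Stellate cell markers rose in 6 of 22, with Col1a1 at 2.52 ± 0.40 and the matrix enzyme Loxl2 at 2.20 ± 0.30, and ductular markers in 3 of 12 (camera adjusted p = 0.000344 and 0.00161, and adjusted p = 0.493 and 0.356 with an estimated correlation). The growth gene, fatty acid oxidation, acute phase and Nrf2 lists were called up, and the fatty acid synthesis, female-biased, T and NK cell and B cell lists down. Their camera adjusted p was 0.000149, 0.0104, 0.0185 and 0.0211 for the former and 0.00746, 0.000344, 0.00744 and 0.0172 for the latter. With an estimated correlation these became adjusted p = 0.217, 0.512, 0.715 and 0.524, and adjusted p = 0.512, 0.389, 0.283 and 0.512.

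Over all genes 2490 changed at 48 h (1169 up, 1321 down), 1190 with the Y-linked transcripts as a covariate and 1553 with no filter on dim genes. With the covariate 19 of the 20 lists kept their calls, and the hepatocyte markers did not (camera adjusted p = 0.0516). Called only there were the neutrophil (median 3.05), macrophage (0.37), interferon (0.36) and fetal liver (1.10) lists, up, and the unfolded protein list (-0.79), down. Their camera adjusted p was 9.96e-06, 0.0156, 0.0133, 0.0312 and 0.00949 (adjusted p = 0.510 to 0.636 with an estimated correlation). These values, too, rest on the slope that the covariate took from the genotype pairs. Without 1 array the count was 628 (Mxcre-negative 0 h), 203 (Mxcre-positive 0 h), 986 (either 24 h array), 1470 (either 36 h array), 86 (Mxcre-negative 48 h) and 363 (Mxcre-positive 48 h). Scaling by the median of the array moved the split to 1633 up and 864 down.

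The last comparison asks whether the genotype difference after hepatectomy was other than before it. The 0 h difference came from 1 pair of arrays and its spread was taken from the pairs of 24, 36 and 48 h, so a departure of 1 array at 0 h was enough for a call. It called 24 of 14142 genes, 22 with a more positive and 2 with a more negative difference after surgery, and 945 genes had an unadjusted p under 0.05. The smallest p were those of the phosphatase subunit Ppp2r5a (9.21 ± 0.22), above background on all arrays, and of Atp6v0b, a proton pump subunit, Gas2l1, Pcsk1n and Cdr2l (limma adjusted p = 0.0147 for each). The last 4 were not above background on the Mxcre-positive 0 h array, and with it at their bound the change was at least 8.28, 6.10, 5.81 and 4.66. Mxra7 (at least 2.13 more negative at its bound, limma adjusted p = 0.0341) had a more negative difference, and Hspa1a, Jph3 and Polr2h did not pass (limma adjusted p = 0.0579, 0.0651 and 0.0586). In 20 of the 24 the value on the Mxcre-positive 0 h array lay more than 3 log2 units from the other 7 arrays, which spanned less than 2. That array also had the most outlier spots (131, against 47 to 80 on the others). No gene was called without the pair of 24 h, of 36 h or of 48 h, with 36 and 48 h against 0 and 24 h, with the Y-linked covariate, or without genes that departed on 1 array. There were 4 called with normexp correction and 3 among genes above background on all arrays.

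**Figure D5:**
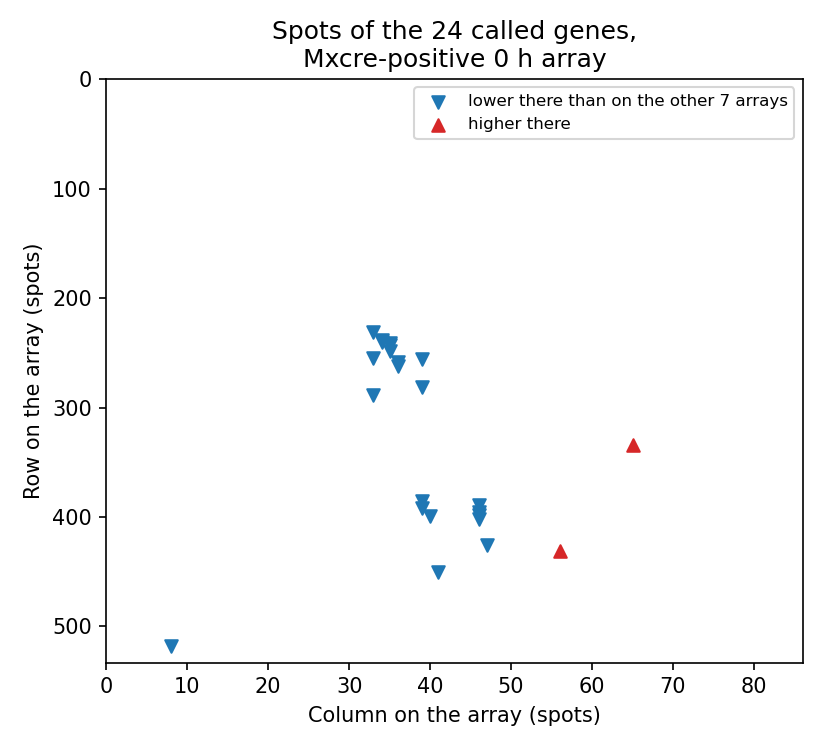
Position on the Mxcre-positive 0 h array (column and row of the spot grid) of the 24 genes whose genotype difference changed after hepatectomy, with downward triangles for genes lower and upward triangles for genes higher there than on the other 7 arrays. Most lie in a band between rows 231 and 450.

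As groups, neutrophil and macrophage markers had a more positive genotype difference after surgery and replication genes a more negative one. The 13 neutrophil markers were all more positive (median 3.81, or 3.16 with 3 members at a bound on some arrays), with Mpo at 4.72 ± 2.02 and Elane at least 3.16, both granule enzymes, and 2 passed adjusted over the list alone (camera adjusted p = 1.5e-08). Of 21 macrophage markers 19 were more positive (median 0.96), with the lysozyme Lyz2 at 3.71 ± 0.28 (1 adjusted over the list alone; camera adjusted p = 2.01e-05). S phase genes were more negative in 33 of 35 (median -0.66, or -0.50 with 4 at a bound on some arrays, camera adjusted p = 4.96e-07) and male-biased genes in 14 of 14 (median -1.19, camera adjusted p = 4.12e-07). Unfolded protein and heat shock genes were more negative in 18 of 20, with the heat shock gene Hspa1b at -2.69 ± 0.43, while Trib3 stood at 2.25 ± 0.25 (1 up and 3 down adjusted over the list alone, camera adjusted p = 6.12e-05). With an estimated correlation each of these 5 lists had adjusted p = 0.692. With the Y-linked covariate the neutrophil and male-biased lists kept their calls, and the macrophage, unfolded protein and S phase lists did not (camera adjusted p = 0.0585, 0.0585 and 0.912). The covariate took up what was confined to the late pairs, so that fit compared mainly the pair of 24 h with that of 0 h. The cytochrome P450, fatty acid oxidation and clock lists, more negative, and the B cell list, more positive, were called only there (camera adjusted p = 0.000173, 0.0189, 0.031 and 0.00407, and adjusted p = 0.956 for each with an estimated correlation). No listed gene passed over all genes, and of 34 lists 13 were called, 5 up and 8 down.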

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

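The tests of the S phase pattern and the alternatives with the Y-linked transcripts as a covariate, with genes that depart on 1 array left out, and for lists with 36 and 48 h set against 0 and 24 h, were chosen after the results were seen; the tests on spots and splits were set before.

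The genotype difference after hepatectomy was other than at 0 h, by the test of that change, in 24 genes and 13 gene lists. The 0 h side of this test was 1 pair of arrays, with its spread taken from the later pairs, so it cannot separate a change after surgery from a departure of 1 array at 0 h. The lists with a more positive difference after surgery were the neutrophil markers (median 3.81, or 3.16 with dim arrays at their bound), the macrophage markers (0.96), the interferon-stimulated genes (0.52), the acute phase proteins (0.45) and the female-biased genes (0.39). Those with a more negative one were the Y-linked genes (-4.45, or -1.40 with dim arrays at their bound), male-biased genes (-1.19), chromosomal passenger partners (-0.69, or -0.38 so), S phase genes (-0.66, or -0.50 so), unfolded protein and heat shock genes (-0.48), mitosis genes (-0.32, or -0.08 so), urea cycle genes (-0.26) and plasma proteins (-0.16). None of the 13 was called with an estimated correlation (adjusted p = 0.692 to 0.770). With the Y-linked covariate 5 of the 13 kept their calls and directions, and the S phase list, for example, did not (camera adjusted p = 0.912). That fit compared mainly the pair of 24 h with that of 0 h, so differences confined to the late pairs were lost in it whatever their cause. With 36 and 48 h against 0 and 24 h 9 of the 13 kept their calls and directions and 1 turned.

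The 8 splits of the arrays that swap genotypes within times are too few for a share under 0.05. For the changed difference 4 of the 8 gave as many genes as the real 24, and the highest other gave 29. For genotype all 8 gave as many genes as the real 0 (highest other 0), and 5 of the 8 gave as many lists as the real 12 (highest other 14).

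The first pattern weighed is the set of 24 genes, 20 of which depart on the Mxcre-positive 0 h array alone. A genotype difference of these genes before surgery would be seen by their other probes, but in the 6 genes with other probes these showed a median of 0.0205 of the departure (quartiles -0.0395 to 0.0463), which argues against it for those 6. The spots lay a median of 5.5 spots from the nearest other called gene on that array, against a median of 22.0 and a 5th percentile of 15.5 in 10000 random sets of 24. Both values are what a damaged area, with signal lost at single spots, would give, so the calls may come from the array rather than the liver. For the genes with no other usable probe, among them Mxra7, which was higher there, a difference of the gene itself stays open.

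The second pattern is the lower level of S phase transcripts in Mxcre-positive liver at 36 and 48 h (median difference -1.10 over both times, quartiles -1.33 to -0.77, 35 genes). A smaller share of hepatocytes would lower hepatocyte markers by about as much, but their median was -0.11 (quartiles -0.21 to 0.15, 8 genes). A cycle that ran later by the time between samplings would let these transcripts go on rising from 36 to 48 h in Mxcre-positive liver. But 30 of 35 were lower at 48 h (median -0.32, and -0.15 with 22 lower in Mxcre-negative liver). Each time had 1 array per genotype, and the values do not bear on a shorter delay. Sex stays open, since 0 of the 2 late pairs were alike in Y-linked signal. With the covariate the median of this list over all times went from -0.52 (quartiles -0.62 to -0.37) to 0.01 (-0.16 to 0.31), without a genotype call (camera adjusted p = 0.386). This does not bear on sex. Y-linked signal differed clearly within pairs only at 36 and 48 h, so the covariate takes up any difference confined to these pairs. A weaker S phase response after loss of Survivin is a candidate explanation, untested here because genotype and sex cannot be told apart at these times.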

How the results depend on the processing

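The alternatives with the Y-linked transcripts as a covariate, with genes that depart on 1 array left out, with lists tested on the 0 and 24 h pairs alone, and for lists with 36 and 48 h against 0 and 24 h, were chosen after seeing the data. The Birc5 difference kept its sign in all 18 alternatives, from -2.15 to -4.68 (main value -3.71, and -2.15 with normexp correction), and passed the threshold in none. Several of these, such as the other filters and models, leave its value as it is. The number of genes changed by genotype was 0 in all 18 other fits; without a correction for multiple tests it was 32 (11 up, 21 down) at p under 0.01 with a 2-fold change, and 7 genes (2 up, 5 down) had a 2-fold difference at all 4 times.

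The counts after hepatectomy moved as well. At 24 h (1369 genes) they were 2191 with normexp correction, 2152 with trended and robust variances, 573 with no filter on dim genes and 1 with the Y-linked covariate. At 36 h (2298 genes) they were 938 with no filter and 984 with the covariate, and at 48 h (2490 genes) 1553 and 1190. With no filter more genes were tested. Leaving out 1 array, which takes a residual degree of freedom, gave 0 to 514 genes at 24 h, 0 to 903 at 36 h and 86 to 1470 at 48 h. Where an array left a time with 1 array, that array was assumed to vary like the others. The other alternatives gave 1218 to 2035, 1985 to 2810 and 2308 to 2905 genes. The larger direction, down in the main fits, turned with quantile normalisation (771 up and 712 down at 24 h, 1161 and 931 at 36 h, 1324 and 1100 at 48 h) and with the array median (888 and 622, 1875 and 704, 1633 and 864), and also at all 3 times with normexp correction and the deposited matrix. It turned at 24 and 36 h with trended and robust variances, at 24 h among genes above background on all arrays (1018 and 1017), at 36 h with the mean of probes and with no filter, and at all 3 times with the Y-linked covariate (1 and 0, 565 and 419, 646 and 544). Without 1 array it turned at 36 h wherever genes were called. At 24 h it turned without the Mxcre-negative 0 h array but not without either 48 h array. At 48 h it turned except without either 36 h array.

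The count of changed genotype differences (24) was 4 with normexp correction, 3 among genes above background on all arrays, 0 without any 1 of the pairs of 24, 36 and 48 h, 0 with 36 and 48 h against 0 and 24 h, 0 with the Y-linked covariate and 0 without genes that depart on 1 array. The other 6 alternatives gave 17 to 27.

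With an estimated correlation 0 lists were called for genotype, at 24, 36 or 48 h, or for the changed difference. Fry's directional p called 0 lists for genotype, 9 at 24 h, 11 at 36 h, 12 at 48 h and 0 for the changed difference, and its mixed p 5, 25, 23, 28 and 0. With the Y-linked covariate 10 lists were called at 24 h in place of 16, with 7 of the 16 kept. The other alternatives stayed within 1.5 times of the counts, though not always with the same lists. Without 1 pair of arrays 14 to 16 lists were called for genotype, with 9 to 12 of the 12 kept, and 1 turned without the pair of 48 h. The pairs of 0 and 24 h alone gave 11 lists, with 5 of the 12 kept and 1 turned. With the covariate 10 lists were called for genotype. Of the first 12, 5 kept their call and direction. The other 5 called were the neutrophil, macrophage, progenitor and interferon lists, lower, and the stellate cell list, higher. Camera gave another 5 of the first 12 the opposite direction without a call, with small medians. Among these was the Y-linked list, which was tested with its own mean as the covariate, so that its loss was fixed beforehand.

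Among the single named genes, 850 comparisons with an alternative kept direction and side of the threshold and 178 kept direction without passing. Another 2 passed only under the alternative and 0 reversed. Genes named for genotype or a time had been chosen for 1 sign over the times or in both genotypes. Several alternatives also leave the difference as it is, so the lack of reversals was largely fixed beforehand. Probes of 1 gene differed in sign in 1847 of 4926 genes for genotype, and among the called genes with other probes in 52 of 490, 84 of 741 and 84 of 806 at 24, 36 and 48 h. Signal over background limits the folds of genes that were dim at 0 h. Except where the number of genes or arrays is named, the cause was not tested.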

Other observations

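The tests on the sex chromosome transcripts were chosen after the result was seen. Birc5 and the mitotic genes can be compared within each genotype, as values without a test. From 0 to 48 h Birc5 was 5.29 higher (log2) in Mxcre-negative liver, where the median of 38 mitosis genes was 4.77 higher (quartiles 3.19 to 5.52, with 20 of them at the background level at 0 h). In Mxcre-positive liver Birc5 was 1.60 higher while the mitosis genes had a median of 4.42 (19 at that level), and 2 of the 38 were less raised than Birc5. With the same bound S phase genes were 2.40 higher at 48 h in Mxcre-negative and 1.47 higher in Mxcre-positive liver.

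Several groups with no list call at a time still held genes that passed after hepatectomy. Of 18 clock genes 7 fell and 3 rose by 24 h, with Per3 at -4.04 ± 0.34 (at least 3.60 lower at its bound) and Dbp at -4.02 ± 0.33 (10 and 4 adjusted over the list alone; camera adjusted p = 0.0690). Afp, the fetal albumin-like protein, rose by 3.64 ± 0.54 at 48 h, the only one of 11 fetal liver genes to pass (3 adjusted over the list alone; camera adjusted p = 0.0608). The lactate dehydrogenase gene Ldha rose by 1.28 ± 0.14 at 36 h, and the glycolysis and gluconeogenesis list was not called (camera adjusted p = 0.709). Among cell markers, the endothelial and progenitor gene Cd34 rose by 1.67 ± 0.15 and Ly6c1, a member of the macrophage list, by 2.32 ± 0.35 at 48 h. Stab2, a sinusoidal endothelial receptor, stood at -0.89 ± 0.13 and Car1, an erythroid carbonic anhydrase, at -1.78 ± 0.23, both past the threshold. Of 23 apoptosis regulators 4 rose at 48 h, with Bax at 0.89 ± 0.15, Bak1 at 0.83 ± 0.15 and Bcl2l1 at 0.78 ± 0.16 (camera adjusted p = 0.678).

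The third pattern weighed is the way Y-linked transcripts and Xist vary over the arrays. With 1 sex per sample, Xist would be at background wherever Y-linked genes are seen, but it was well above background on 4 of the 4 arrays with Y-linked signal. RNA of both sexes in 1 sample would give Xist levels below those of the other arrays, and the highest on an array with Y-linked signal was 4.44 against a lowest of 5.16 on the others. Transplanted marrow cells of the other sex may also give both signals: Xist on these 4 arrays was 14.6% to 60.9% of the lowest level on the others. Male-biased liver genes had mean levels of 3.88 to 4.74 on these arrays and 2.57 to 3.66 on the others, which would go with male liver RNA rather than marrow cells alone. But in the 24 h pair, alike in Y-linked signal, all 14 were lower in Mxcre-positive liver. Female-biased levels overlapped (1.07 to 2.55 against 2.09 to 3.57). With no donor sex in the labels, a pool of livers and a transplant cannot be told apart. No biological explanation in terms of genotype was tested.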
